A study of Homo sapiens with 4 samples.

How the data were processed

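The 4 libraries were grouped by cell line and transfected oligonucleotide, as the labels name them, with 1 library per group: MIA PaCa-2 with the mimic, MIA PaCa-2 with the scramble, PSN-1 with the mimic and PSN-1 with the scramble. Per the labels' protocols, RNA was isolated with a miRNeasy Micro kit and libraries were made with a TruSeq stranded mRNA kit, which selects polyadenylated RNA, so mature microRNAs are not measured and MIR4800 was listed at 0 in all 4 libraries. The deposited values are FPKM per gene symbol, per the file headers. The submitters' processing notes name TopHat2 2.1.1, Cuffdiff 2.2.1 and the genome build hg19, without saying what each was used for; the annotation, the strand setting and any scaling between libraries are not given in the sources used here. FPKM divides by transcript length and by library total, so a few abundant genes can move all others; the 10 highest genes took 7.39% to 7.99% of the summed FPKM.

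Depth was estimated from low values. Where a gene was under 0.3 FPKM in both libraries of a pair, the most frequent ratio gave the relative worth of 1 fragment, and among gene pairs under 0.1 FPKM, 82.7% to 84.4% of the rescaled ratios lay within 0.5% of a ratio of whole numbers up to 6, against 5.92% of random ratios. The absolute depth came from 32 of 65 single-transcript genes of at least 1000 bases that fell in the modal bin, assuming a fragment length of 200 bases, and is an estimate. A transcript of 2 kb then has about 22.8 fragments at 1 FPKM in the shallowest library (counting SE of a log2 ratio 0.43) and about 1138 at 50 FPKM (SE 0.060). These errors cover counting only.

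With 1 library per group there was no test within a line. Changes were log2 of FPKM with a pseudocount of 1, for genes with a mean of at least 1 FPKM over the line's 2 libraries, and genes past 2-fold were counted. Of 26 gene lists fixed before the data were examined, those with at least 5 measured members were compared with 10000 random lists of the same size drawn within 20 bins of mean expression; a median at or below percentile 2.5 or at or above percentile 97.5 stood apart. Leukocyte markers had 2 measured members in MIA PaCa-2 and 4 in PSN-1, endothelial markers 3 and 5, fibroblast and stellate cell markers 3 and 6, and pancreatic lineage genes 3 and 16. The remaining lists, whose medians lay within the random range in both lines, were cholesterol synthesis (percentiles 3.35 and 63.0), miRNA pathway (41.8 and 94.7), cytosolic ribosomal protein (50.1 and 82.2) and nuclear respiratory chain genes (9.63 and 17.2); in PSN-1 alone, pancreatic lineage genes were at percentile 16.9 and endothelial markers at 11.0. With the filter of 5 FPKM, the pancreatic lineage genes in PSN-1 (median -0.17, percentile 1.99) and the cholesterol synthesis genes in MIA PaCa-2 (percentile 1.98) lay outside the random range.

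The effect shared by both lines was fitted with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with trend) with the line as a block, two-sided, since each line gives 1 mimic and 1 scramble library; the pairing is by cell line, from the labels, which carry no replicate numbers. Its spread is the disagreement of the 2 lines. Lists were tested with camera and fry in the same fit. On simulated data for the mimic effect shared by both lines, 200 of 10678 genes were changed. Limma called 99% of genes changed 2-fold and 100% of genes changed 4-fold, as well as 16 unchanged genes. Those changes were the same in both lines, in genes of at least 5 FPKM, so the rates leave out disagreement between lines. They do not give the power on the real data, where SNRPE and LSM6, past 2-fold in both lines, were not called in the main fit (adjusted p = 0.0655 in limma for both). For gene lists in MIA PaCa-2, 100 simulated lists of 30 genes among 11484 were placed at or above percentile 97.5 in 4 cases with no shift, 92 with a shift of 0.2 and 100 with a shift of 0.5. Simulated members were drawn at random from shuffled changes, so these cases do not give the rates for lists whose genes vary together.

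Seed sites were searched in the longest annotated 3' UTR of each protein-coding gene of GENCODE (GRCh38, another build than the hg19 of the files), joined on gene symbol and older symbols: 18695 of 26255 symbols matched, and 11534 of the 12423 with a mean of at least 1 FPKM. Sites were the 8mer GACGGATA and the 7-mers GACGGAT and ACGGATA, compared with genes without ACGGAT, and random lists were matched in 5 bins of expression by 5 bins of 3' UTR length. The 7-mer rank covered 7-mers found in at least 30 genes. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

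Named genes were chosen by a rule fixed before the data were examined: in each line the 10 highest and 10 lowest changes at a mean of at least 5 FPKM, leaving out short non-coding genes by symbol and symbols listed more than once with different values; the 10 lower and 10 higher genes in both lines by the smaller absolute change; the 10 lowest seed site genes; up to 4 members of each list that stood apart; and MXD4, STK25, VIM, CDH1 and ZEB1. Some lists and genes that this rule covers are not reported here. The alternatives were pseudocounts of 0.1 and 5, no filter and a filter of 5 FPKM, median-ratio and TPM scaling, a 1.5-fold threshold, other kinds of seed site, the mean for the median, unmatched random lists, limma without block or trend, and each line alone. Leaving out short non-coding genes and removing the trend on 3' UTR GC content (medians of 50 bins) were added after seeing the data.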

Results

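RNA was sequenced from PSN-1 and MIA PaCa-2, 2 human lines derived from pancreatic tumours, each transfected with a synthetic mimic of the microRNA miR-4800-3p or with a scrambled control oligonucleotide. Each of the 4 combinations of line and oligonucleotide had 1 library, so no value below has a replicate within its line, and the only repeat of the treatment was the second line. The stated purpose was to look for messenger RNAs targeted by miR-4800-3p, with an interest in metastasis. The values were FPKM for 26255 gene symbols, and 15699, 15747, 17294 and 16783 of them were above 0 in the MIA PaCa-2 mimic, MIA PaCa-2 scramble, PSN-1 mimic and PSN-1 scramble libraries. From whole-fragment steps among low values, 1 FPKM was estimated to stand for 14.2, 12.7, 15.9 and 12.6 fragments per kb of transcript in the same order. At the depth of the shallowest library, a 2 kb transcript at 5 FPKM rests on about 114 fragments, which gives a log2 ratio a counting error of about 0.19 (SE), without any error between cultures. Changes below are log2 of (mimic FPKM + 1) over (scramble FPKM + 1), a scale that understates the change of low genes.

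In MIA PaCa-2, the highest changes included inflammatory and stress genes and the lowest included genes of splicing and cell division, in 1 pair of libraries. CXCL8, the neutrophil-attracting chemokine interleukin 8, was at 478 FPKM with the mimic and 70.6 with the scramble (log2 change 2.74), and HMOX1, the heme-degrading enzyme heme oxygenase 1, was at 568 against 95.7 FPKM (2.56). CXCL1, another chemokine gene, was at 642 against 243 FPKM (1.40). The transcription factors EGR3 (1.88) and CEBPB (1.83) and the mitochondrial phosphatase PTPMT1 (2.49) were also among the highest changes. The lowest changes included RNF220, a ubiquitin ligase (1.03 against 10.3 FPKM, log2 change -2.48), the splicing protein genes LSM6 (-1.63) and SNRPE (-1.55), the mitotic kinesin gene KIFC1 (5.25 against 16.7 FPKM), the G protein regulator RGS3 (-1.42), the DNA ligase gene LIG1 (-1.41), the ATP synthase subunit gene ATP5I (-1.41) and LMTK2 (-1.34).

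Among the gene lists measured in MIA PaCa-2, 31 of 32 G2/M proliferation genes were lower with the mimic, 13 of them past 1.5-fold, with a list median of -0.51 at percentile 0 of 10000 random lists matched on expression. PLK1, a mitotic kinase, was at 24.0 against 52.5 FPKM (-1.09), and the cyclin gene CCNA2 was at 9.42 against 18.2 FPKM (-0.88). Of 36 G1/S and DNA replication genes 33 were lower (median -0.42, percentile 0), among them RRM1, a subunit of ribonucleotide reductase (-1.05), and MCM10 (-0.85). Of 19 NF-kB and inflammatory cytokine genes 16 were higher (median 0.48, percentile 100), and BIRC3 was at 13.1 against 5.86 FPKM (1.04). Of 27 unfolded protein and integrated stress response genes 22 were higher (median 0.33, percentile 100), including TRIB3 (1.09) and ATF3 (0.92), while SDF2L1 was lower (-0.61). These percentiles describe this pair of libraries. In the fit of both lines none of these 4 lists was called by camera with an estimated correlation (adjusted p = 0.748 for each). That setting rests on 1 residual degree of freedom and called no list at all, so it cannot decide for or against them. Of 29 p53 target and apoptosis genes 22 were higher (median 0.23, percentile 99.9), with GADD45A at 1.11 and MCL1 at 0.90. In the fit of both lines the p53 list was not called by camera with a preset correlation either (adjusted p = 0.0518). The 30 common reference genes had a median of -0.072 at percentile 2.49, with IPO8 at -0.98, POLR2A at -0.61, RAB7A at 0.84 and TBP at 0.86. Of the alternatives run, the 5 FPKM filter alone kept this list outside the random range, and the others put it inside (percentile up to 6.85). Interferon-stimulated genes (percentile 57.2) and hypoxia and glycolysis genes (percentile 78.3) lay within the random range in MIA PaCa-2.

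Over all genes in MIA PaCa-2 with a mean of at least 1 FPKM, 151 of 11484 were higher and 93 lower past 2-fold. The median change of these genes was 0.014. Short non-coding genes, in which a single fragment can be worth many FPKM, made up 32 of the 151 and 33 of the 93. SNAR-E, listed at 0 with the mimic and at 15.8 FPKM with the scramble, rested on values of this kind. MTRNR2L8, MTRNR2L9 and MTRNR2L2, nuclear copies of mitochondrial ribosomal RNA whose reads can come from the mitochondrial genome, had log2 changes of 1.95, 1.94 and 1.85, and the MTRNR2L genes took 0.289% of the summed FPKM with the mimic against 0.0784% with the scramble.

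In PSN-1, the immediate-early and activity-regulated transcription factor genes were among the highest with the mimic. NR4A1 was at 79.5 against 22.5 FPKM (log2 change 1.77), NR4A2 at 36.3 against 9.30 FPKM (1.86), FOSB at 110 against 34.9 FPKM (1.63), and GEM, a small GTP-binding protein gene, at 199 against 62.9 FPKM (1.65). DUSP8, a phosphatase of MAP kinases, was at 9.28 against 1.22 FPKM (2.21), and ARL14 was at 9.06 against 2.04 FPKM (1.73). ALDH1A3, an aldehyde dehydrogenase that makes retinoic acid, was at 11.7 against 50.4 FPKM (-2.02). AMIGO2 (-1.71), AGPAT9, an enzyme of triglyceride synthesis (-1.69), WRB (-1.66), PTGIS, the prostacyclin synthase gene (-1.48), and PLIN4 (-1.47) were among the other lowest changes. AMIGO2, PTGIS, PLIN4 and ARL14 were each under 0.1 FPKM in both MIA PaCa-2 libraries, which left no comparison there.

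Interferon-stimulated genes were lower in the PSN-1 mimic library in 30 of 38 measured members (median -0.22, percentile 0.01), with IFIT2 at 2.13 against 5.73 FPKM (-1.11) and UBE2L6 at 36.2 against 71.9 FPKM (-0.97). The percentiles here describe 1 pair of libraries. In the fit of both lines camera did not call the interferon list (adjusted p = 0.251 with a preset correlation). G1/S and DNA replication genes were lower in 30 of 36 (median -0.22, percentile 0) and G2/M proliferation genes in 25 of 32 (median -0.16, percentile 0.33), although none of the 32 passed 1.5-fold. CCND3, a cyclin in the G1/S list, was higher (36.2 against 18.5 FPKM, 0.93). NF-kB and inflammatory cytokine genes had a median of 0.12 at percentile 99.2, with 16 of 26 higher, among them CXCL8 (1.02), BIRC3 (0.96) and CXCL1 (0.61). With the trend on 3' UTR GC content removed, a step chosen after seeing the data, that median was 0.21 (percentile 100), with 14 of the 25 NF-kB genes that have a 3' UTR higher. Unfolded protein and integrated stress response genes were higher in 17 of 28 (median 0.093, percentile 98.4, and 97.1, inside the random range, with lists not matched on expression), with ATF3 at 99.7 against 41.7 FPKM (1.24) and TRIB3 at -0.28. Of 30 hypoxia and glycolysis genes 19 were higher (median 0.12, percentile 99.8), including the glucose transporter gene SLC2A3 (0.71), KDM3A (0.61) and ENO2 (0.50). Camera did not call this list in the fit of both lines (adjusted p = 0.089 with a preset correlation). The 6 measured fibroblast and stellate cell markers had a median of -0.29 at percentile 1.34, with COL3A1 at -0.33 and RGS5 at 0.46, and at percentile 5.10 without the filter on low values. The p53 target and apoptosis genes (percentile 74.7) and common reference genes (percentile 17.0) lay within the random range in PSN-1, and for no list was the difference between the lines tested.

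Past 2-fold, 104 of 12233 genes were higher and 95 lower in PSN-1, and the median change was -0.016. Short non-coding genes made up 33 of the 104 and 20 of the 95. H3F3A was at 0.0127 FPKM with the mimic and 22.0 with the scramble, while its near-identical copy H3F3AP4 was at 173 against 54.1 FPKM, so these reads can be split between copies and both values are uncertain. Across genes, the PSN-1 changes followed the GC content of the 3' UTR (Spearman correlation -0.219, genes not being independent replicates), while that in MIA PaCa-2 was -0.00914.

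By the smaller of the 2 changes, SNRPE and LSM6 led the genes lower in both lines, and SNHG25 and NUDT4P1, which rest on few or shared reads, led those higher in both lines. SNRPE, a core protein of spliceosomal particles, was at 5.48 against 17.9 FPKM in MIA PaCa-2 (log2 change -1.55) and had a log2 change of -1.62 in PSN-1. LSM6, a protein of the U6 particle, had log2 changes of -1.63 and -1.53, and ATP5I of -1.41 and -1.44. AGPAT9 (-1.16 and -1.69), NAA38 (-1.25 and -1.12), the deubiquitinase gene STAMBPL1 (-1.11 and -1.22), MLLT6 (-1.04 and -1.08), PTGES2 (-1.04 and -1.40), RGS3 (-1.42 and -1.02) and WRB (6.06 against 13.1 FPKM in MIA PaCa-2 and 5.61 against 19.9 FPKM in PSN-1) completed the 10 lower genes. After those leading genes, the genes higher in both lines were DUSP8 (1.73 and 2.21), PTPMT1 (2.49 and 1.59), CHMP1B, a component of the ESCRT-III membrane machinery (1.37 and 1.23), the secreted glycoprotein gene STC1 (1.17 and 1.40), the Notch ligand gene JAG1 (1.20 and 1.09), BANF1 (1.07 and 1.11), CXCL8 (2.74 and 1.02) and EGR2 (1.19 and 0.97).

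**Figure D1:**
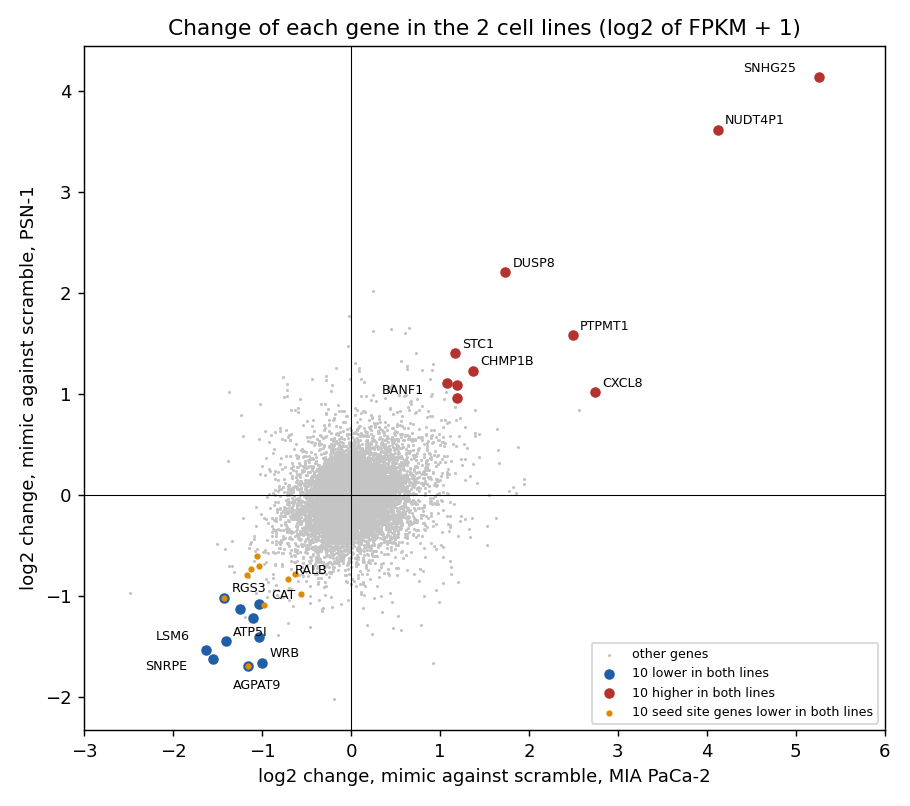
Each point is a gene with a mean of at least 1 FPKM in both lines, short non-coding genes left out; the axes give the log2 change of FPKM + 1, mimic against scramble, in MIA PaCa-2 and in PSN-1, with 1 library per arm. LSM6, SNRPE, ATP5I and AGPAT9 lie below -1 on both axes and DUSP8, PTPMT1, CHMP1B, STC1 and BANF1 above 1 on both.

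Of the leading genes of the higher group, SNHG25 was listed at 37.4 and 16.7 FPKM with the mimic and at 0 with the scramble in both lines, and its depth-corrected mimic values stood in the ratio 2 to 1, the ratio of 2 fragments to 1. NUDT4P1 was at 17.0 and 12.4 FPKM with the mimic and at 0.0344 and 0.0891 with the scramble, while the related copy NUDT4P2 was at 9.33 against 25.8 FPKM in MIA PaCa-2 and 28.6 against 47.1 FPKM in PSN-1, so reads can have been split between them.

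Limma, fitted to log2(FPKM + 1) with cell line as a block and 1 residual degree of freedom, called 6 genes higher and 1 lower at a Benjamini-Hochberg adjusted p under 0.05 among 10678 genes. ATP5I was the lower one (mean log2 change -1.43, SE 0.0998, adjusted p = 0.0159 in limma), and it was not called without the trend, without the filter or without the line as a block. The higher ones were NUDT4P1 (adjusted p = 0.00533 in limma), SNHG25 and the small nucleolar RNA genes SNORD82, SNORD105B, SNORD50A and SNORA31, and those 5 genes were listed at 0 in both scramble libraries with mimic values worth 1 or 2 units of the smallest step. Limma's calls moved to 27 higher and 21 lower with median-ratio scaling and to 13 higher and 10 lower with TPM scaling. The TPM setting also raised all values, from a summed FPKM of at most 510908 per library, against an unchanged pseudocount and filter. With it 11575 genes entered the fit, so its counts do not show the effect of scaling between libraries alone. With short non-coding genes left out, an alternative chosen after seeing the data, 7 genes were higher and 6 lower in limma; DUSP8, BANF1, CHMP1B, JAG1 and EGR1 were then among the higher, and SNRPE, LSM6, AGPAT9, ARHGDIA and VDAC1 among the lower. EGR1, ARHGDIA and VDAC1 were named after their values were seen. Without the line as a block, 0 genes were called by limma in either direction, with 28 higher and 26 lower at an unadjusted p under 0.05.

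Past 2-fold, 16 genes were higher in both lines where independent lists would share 0.742, and 12 were lower in both where independent lists would share 0.287. In opposite directions 13 genes passed 2-fold, where independent lists give 0.949. With short non-coding genes left out, a step chosen after seeing the data, 11 genes were higher and 11 lower past 2-fold in both lines. Across genes the 2 lines' changes had a Pearson r of 0.178 and a Spearman correlation of 0.198, and r was 0.273 without short non-coding genes. The mimic and scramble libraries of a line were far closer to each other (Pearson r of log2 values 0.971 in MIA PaCa-2 and 0.976 in PSN-1) than libraries of different lines (0.832 to 0.840).

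Genes with a miR-4800-3p seed site in the 3' UTR were lower with the mimic in both lines. The mature sequence CAUCCGUCCGUCUGUCCAC lies at positions 48 to 66 of the MIR4800 precursor, on chromosome 4 from 2250077 to 2250156 on the minus strand (GRCh38), within the span of MXD4 (chromosome 4, 2247432 to 2262294, minus strand) and overlapped by 2 annotated MXD4 exons. In MIA PaCa-2, 255 genes with an 8mer or 7mer site had a median change 0.15 lower than genes without a site (difference -0.15), at percentile 0 of random lists matched on expression and 3' UTR length, whose middle 95% ran from -0.021 to 0.059. In PSN-1 the difference was -0.11 for 290 genes, at percentile 0, with a random range of -0.023 to 0.043. Of the site genes, 69.0% were below 0 in MIA PaCa-2 against 46.8% of genes without a site, and 65.9% against 52.3% in PSN-1. With the 8mer alone the differences were -0.21 (20 genes) and -0.12 (25 genes). The site GACGGAT ranked 1 from the lowest of 1760 7-mers with the same CpG and GC content in both lines. Among all 7-mers it ranked 1 of 16333 in MIA PaCa-2 and 12 of 16340 in PSN-1. Sites of the opposite arm, miR-4800-5p, gave 0.025 in MIA PaCa-2 (percentile 29.5) and -0.0068 in PSN-1 (percentile 1.58), and the PSN-1 value was 0.00024 once the trend on 3' UTR GC content was removed, a step chosen after seeing the data.

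**Figure D2:**
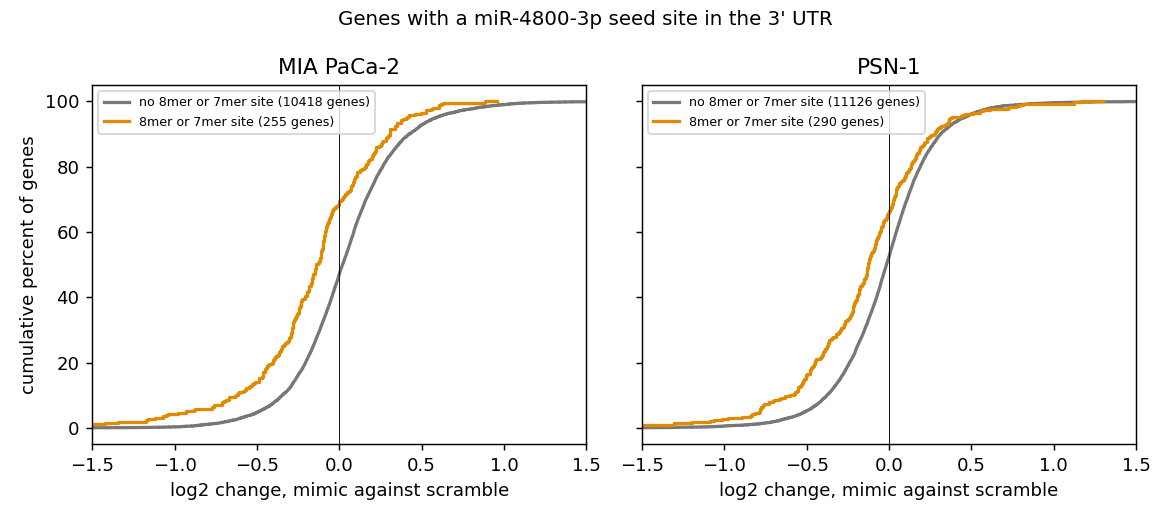
Cumulative percent of genes (vertical axis) against log2 change, mimic against scramble (horizontal axis), for genes with and without an 8mer or 7mer miR-4800-3p site in the 3' UTR, in 1 pair of libraries per line. The curve of the 255 site genes in MIA PaCa-2 and of the 290 in PSN-1 lies to the left of the other curve around 0.

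Among the seed site genes lowest in both lines, AGPAT9 has a GACGGAT site near the start of its 3' UTR on chromosome 4 (83604771 to 83604777, GRCh38, transcript ENST00000395226.6). RGS3 has the 8mer GACGGATA on chromosome 9 (113597073 to 113597080). CAT, the catalase gene, had log2 changes of -0.98 in MIA PaCa-2 and -1.09 in PSN-1 (15.4 against 33.8 FPKM), with its site on chromosome 11 (34471657 to 34471663). RALB, a Ras-like GTPase gene, was at 29.3 against 48.8 and 13.4 against 24.6 FPKM (chromosome 2, 120293271 to 120293277). PLAA (8mer, chromosome 9, 26905489 to 26905496) had log2 changes of -1.12 and -0.73. The tRNA-modifying enzyme gene DUS3L (-1.17 and -0.79), the mitochondrial threonyl-tRNA synthetase gene TARS2 (-1.04 and -0.70), RNF4, a SUMO-targeted ubiquitin ligase gene (-0.63 and -0.78), RRM1 (-1.05 and -0.60) and COMMD6 (-0.56 and -0.98) completed the 10. STK25, a kinase gene with a site on chromosome 2 (241494897 to 241494903), was at 54.4 against 58.3 FPKM in MIA PaCa-2 and 21.5 against 25.4 FPKM in PSN-1 (-0.10 and -0.23). Sites were found in the longest annotated 3' UTR, and their use by these cells was not measured.

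**Figure D3:**
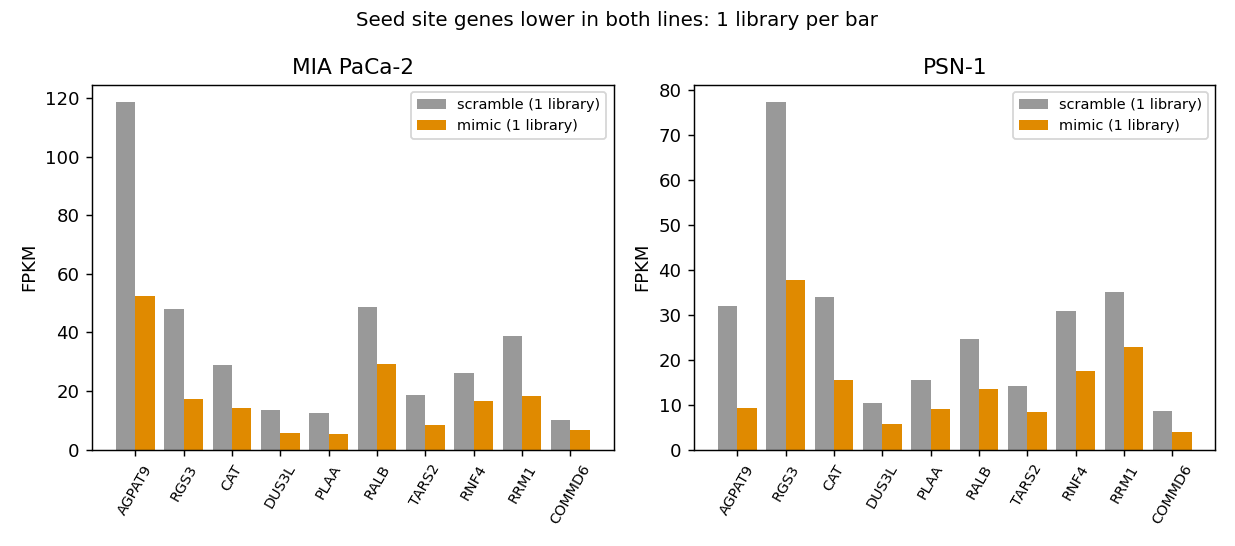
FPKM (vertical axis, from 0) of the 10 seed site genes lowest in both lines, with 1 bar per library for the scramble and the mimic. In both lines each of the 10 genes is lower in the mimic library, for example CAT at 15.4 against 33.8 FPKM in PSN-1.

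Of the 55 searched genes lower past 1.5-fold in both lines, 10 had a 3' UTR site (18.2%, 95% Wilson interval 10.2 to 30.3%), against 243 of 10115 genes measured in both lines (2.40%). None of the 70 genes higher past 1.5-fold in both lines had one (0 of 70, interval up to 5.20%). Both intervals treat genes as independent draws and leave out the spread between cultures. Sites in the coding sequence were present in 11 of the 55, 1 of the 70 and 405 of the 10115 genes, and 35 of the 55 lower genes had neither kind, SNRPE, NAA38, STAMBPL1 and PTGES2 among them. Of the 10 lower genes named above, AGPAT9 and RGS3 had a 3' UTR site, LSM6 and WRB a coding-sequence site, and 6 neither. Genes with a miR-4800-3p site in the coding sequence and no ACGGAT in the 3' UTR were lower in both lines. Their differences were -0.15 in MIA PaCa-2 and -0.079 in PSN-1, both at percentile 0. Coding-sequence sites of the opposite arm also gave differences outside the random range, but in opposite directions, -0.056 in MIA PaCa-2 and 0.034 in PSN-1.

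The metastasis-related lists given here did not stand apart from random lists in either line, as far as their members were measured. Of 25 epithelial genes 13 were measured in MIA PaCa-2 and 18 in PSN-1. Of 28 mesenchymal genes 12 and 17 were measured, and of 29 matrix protease genes 15 and 20. The epithelial junction and keratin genes had medians of 0.14 (percentile 89.8) in MIA PaCa-2 and -0.065 (percentile 21.0) in PSN-1, and the mesenchymal genes 0.10 (percentile 81.6) and -0.094 (percentile 10.6). The epithelial median in MIA PaCa-2 was below 0 without the filter on low values, with the 5 FPKM filter and with TPM scaling (down to -0.076), and without the filter the mesenchymal medians were -0.019 in MIA PaCa-2 and 0.043 in PSN-1. VIM, the intermediate filament vimentin, was at 4401 against 4112 FPKM in MIA PaCa-2 and 1235 against 1144 FPKM in PSN-1, and ZEB1, a repressor of epithelial genes, at 30.5 against 24.1 and 22.7 against 19.8 FPKM. CDH1, the E-cadherin gene, was at 0.335 against 0.170 FPKM in MIA PaCa-2 and 0.720 against 1.51 FPKM in PSN-1, too low to compare. Matrix proteases (percentiles 83.3 and 59.96), integrins (94.7 and 71.3), Hippo core genes (69.6 and 94.1), YAP/TAZ targets (96.7 and 30.2), TGF-beta genes (87.0 and 27.4) and Wnt genes (68.3 and 28.7) lay within the random range in MIA PaCa-2 and PSN-1, except that the YAP/TAZ targets were at percentile 98.8 in MIA PaCa-2 with a pseudocount of 0.1. MXD4, the gene that spans MIR4800, had log2 changes of 0.44 and -0.08.

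**Figure D4:**
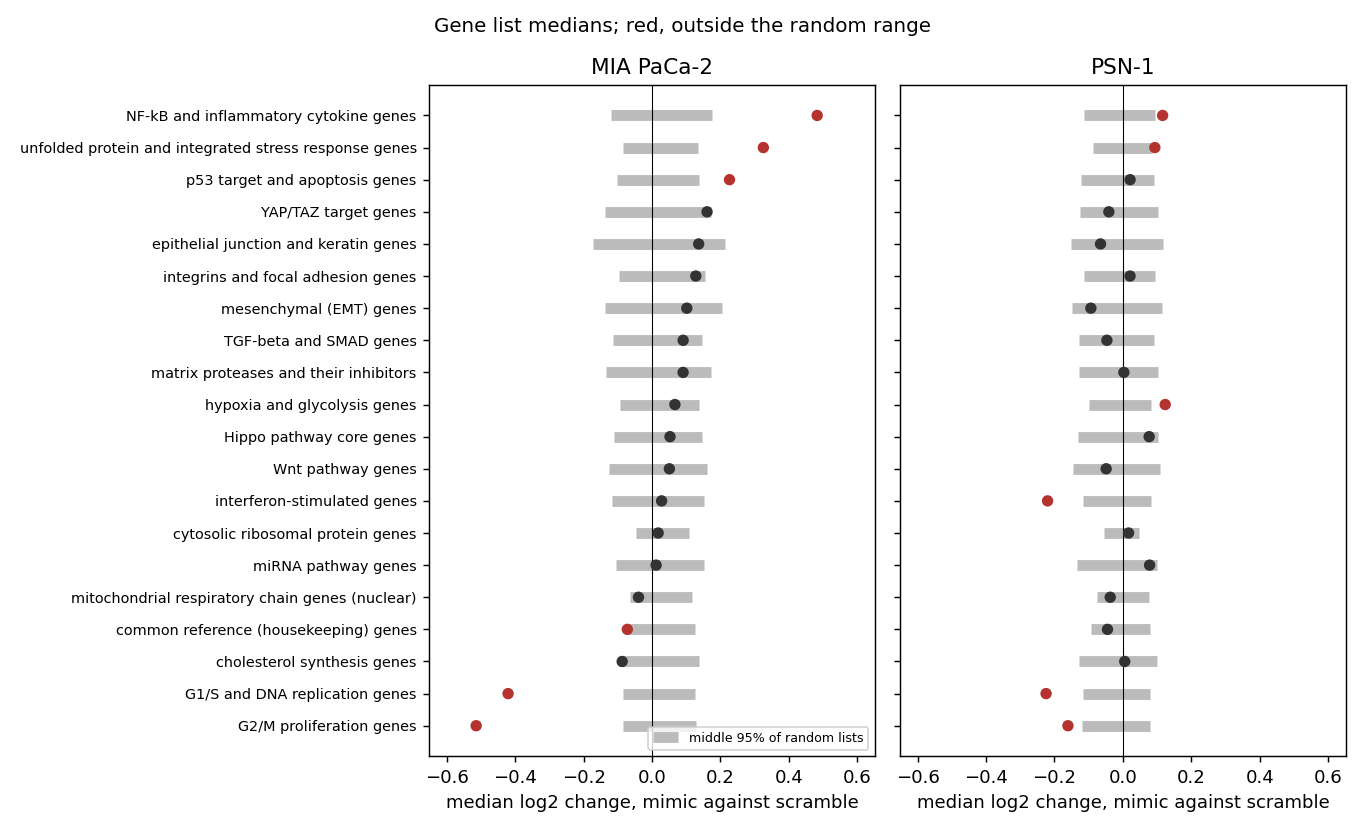
Median log2 change, mimic against scramble, of gene lists with at least 5 measured members in MIA PaCa-2 (points), with the middle 95% of 10000 random lists matched on expression (grey bars); each line has 1 library per arm. G2/M genes lie at -0.51 and -0.16, and NF-kB genes at 0.48 and 0.12, outside the grey bars in MIA PaCa-2 and PSN-1; the lists measured in PSN-1 alone are not drawn.

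In the fit of both lines, camera with a preset correlation gave an adjusted p of 5.6e-10 for the 32 G2/M genes (lower), 7.5e-10 for the 36 G1/S genes (lower), 4.4e-08 for the 18 NF-kB genes (higher) and 0.00029 for the 27 stress response genes (higher). With an estimated correlation, the adjusted p in camera was 0.748 for each of these 4, and fry gave adjusted p-values of at least 0.601. Camera with that setting rests on the fit's 1 residual degree of freedom, and no list tested had an adjusted p under 0.748. For the G2/M, G1/S and stress response genes the estimated correlation was 0.875, 0.289 and 0.282, above the preset one. Their p-values with the preset correlation thus assume less correlation than was estimated. For the NF-kB genes the estimated correlation was -0.046, below the preset one, yet the unadjusted p in camera rose from 6.0e-09 to 0.10. Camera with an estimated correlation therefore cannot decide for or against these lists, and the preset correlation is an assumption. In the main fit no list member passed limma's adjusted p over all genes, though list members did with short non-coding genes left out. Adjusted over the list alone, limma called 7 of the 18 NF-kB genes (CXCL8, CXCL1, CXCL3, NFKB1, RELB, NFKBIA and BIRC3), 4 of the 27 stress response genes, 2 of the 36 G1/S genes and 0 of the 32 G2/M genes. Not all of these went the way of their list. Of the G1/S calls, RRM1 was lower (mean log2 change -0.83) and CCND3 higher (0.81). The stress response calls included ATF3, which was higher (1.08), and SDF2L1, which was lower (-0.63). Over the 26 lists in the main fit, 35 calls in 12 lists were made when adjusted over the list alone, against 0 over all genes. These calls included CLDN1, PKP3 and KRT8 of the epithelial list, SNAI1 of the mesenchymal list and ID1, PMEPA1 and LTBP2 of the TGF-beta list.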

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

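2 named genes passed 1.5-fold in opposite directions in the 2 lines. BCL2L1, an inhibitor of apoptosis, was higher with the mimic in MIA PaCa-2 (log2 change 0.83) and lower in PSN-1 (-0.61), at 38.8 against 21.5 FPKM and 11.7 against 18.4 FPKM. OASL, an interferon-stimulated gene, changed by 0.63 in MIA PaCa-2 (10.6 against 6.51 FPKM) and by -0.74 in PSN-1 (4.25 against 7.79 FPKM). With 1 library per arm the difference between the lines was not tested for either gene, and no explanation was tested.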

How the results depend on the processing

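Leaving out short non-coding genes and removing the GC trend were tests chosen after the result was seen. The miR-4800-3p site difference kept its sign and stayed below the random range in both lines under each alternative run, from -0.21 to -0.081 in MIA PaCa-2 and from -0.12 to -0.070 in PSN-1. The medians of the G1/S, G2/M and NF-kB lists kept their direction and their side of the random range in both lines, as did the p53 list in MIA PaCa-2 and the interferon and hypoxia lists in PSN-1. The stress response list in PSN-1 lay at percentile 97.1 with unmatched lists, and the reference genes in MIA PaCa-2 lay inside the range under most alternatives (percentile up to 6.85). The fibroblast list in PSN-1 lay inside it with a pseudocount of 5 and without a filter (percentile up to 5.10). The counts moved with the threshold, the pseudocount and the low genes, and the cause was not tested except where fewer genes entered. At 1.5-fold, 624 genes were higher and 466 lower in MIA PaCa-2, 388 and 473 in PSN-1, and 80 and 65 in both. With a pseudocount of 0.1 the counts were 249 and 178 in MIA PaCa-2 and 176 and 173 in PSN-1; with 5 they were 80 and 38, 52 and 35, and in both lines 10 and 3. With a filter of 5 FPKM, which tests fewer genes, 54 were lower in MIA PaCa-2, and 59 higher and 61 lower in PSN-1. With TPM scaling 174 were lower in MIA PaCa-2, and 178 higher and 150 lower in PSN-1. TPM values lie above the FPKM values here, so this setting also weakens the pseudocount and the filter. Without short non-coding genes 60 were lower in MIA PaCa-2 and r between lines was 0.273. Limma called 10 higher and 6 lower with a pseudocount of 5, 13 and 10 with TPM scaling, 27 and 21 with median-ratio scaling, 2 lower with the 5 FPKM filter, 6 lower without short non-coding genes, and 0 lower without the trend (513 lower at an unadjusted p under 0.05). Without a filter it called 0 and 0 (563 higher and 566 lower at an unadjusted p under 0.05), and without the replicate block, pairing by line left out, 0 and 0. The control arm miR-4800-5p gave -0.0014 in PSN-1 without a filter and -0.0087 with the 8mer alone, and changed sign there with the 5 FPKM filter (0.0012), coding sites (0.034), the mean (0.0093) and the GC trend removed (0.00024); with coding sites it was -0.056 in MIA PaCa-2. The named genes' values and the other list medians were the same in 2337 of their alternatives, moved in 89, became called in 47, lost a call in 17 and reversed in 0. By the rule used, a change of sign counted as reversed only where the main value was called, outside the random range or at least 2-fold. Other changes of sign, such as the epithelial median in MIA PaCa-2 and the mesenchymal median in PSN-1, are among the 89. Without either line the mean change is the other line's value. Depth limits genes under 5 FPKM, where counting alone gives a log2 ratio an SE above 0.19 for a 2 kb transcript.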

Other observations

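Several genes outside the fixed rule were named after their values were seen. With the mimic, HRAS, MAPK3 and VDAC1 were lower in both lines and EGR1 was higher in both. HRAS was at 22.0 against 40.1 FPKM in MIA PaCa-2 and 19.4 against 39.5 FPKM in PSN-1 (log2 changes -0.84 and -0.99), and MAPK3, the kinase ERK1, at 22.3 against 40.2 and 13.8 against 27.5 FPKM (-0.82 and -0.94). VDAC1, a channel of the outer mitochondrial membrane, had log2 changes of -0.94 and -1.01. The immediate-early gene EGR1 was at 1028 against 696 and 1247 against 747 FPKM.

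For the patterns below, the tests of 3' UTR composition and few fragments on the seed site genes, and the split of the proliferation test by list, were chosen after the result was seen. The first pattern is the lower level of seed site genes in both lines. Base composition of the 3' UTR as the whole cause is argued against by the difference closest to 0 of the 2 lines after the GC trend was removed (-0.11, below all random lists), and genes with few fragments by the same value at 5 FPKM or more (-0.11). If the mimic's seed acted on the same genes in both lines, their changes might be more alike than those of other genes: over 243 site genes Pearson r was 0.388 (bootstrap range 0.247 to 0.520), at percentile 89.7 of matched random lists, short of the limit set beforehand. The bootstrap range includes that limit's r of 0.474. An equal fall of all site genes would also lower their median without raising r. This test therefore cannot decide, and seed pairing stays an open hypothesis.

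The second pattern was found by ranking motifs in MIA PaCa-2, where 493 genes with GACGTA in the 3' UTR were higher with the mimic than genes without it (difference 0.15). A candidate explanation is that the scramble oligonucleotide has a seed of its own and lowers these genes in the control library. Tested in PSN-1, which played no part in choosing the motif, the 526 genes differed by 0.11, with a median at percentile 100 of random lists matched on expression and 3' UTR length. Composition of the motif is argued against there, since GACGTA ranked 1 from the highest of 320 hexamers with 1 CpG and 3 G or C, the top 0.313%. The sequence of the scramble is not given in the sources used here, so a match to it was not analysed.

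The third pattern is the lower level of both proliferation lists. Composition of the 3' UTR is argued against, since after the GC trend was removed the highest percentile of the 4 medians was 0.01. Without members that hold ACGGAT in the coding sequence or 3' UTR, the G2/M list in PSN-1 lay at percentile 2.63 (median -0.12), above the limit of 2.5 set beforehand by less than its sampling error of 0.16, so sites in its own genes stay open there. The other 3 medians stayed at percentile 0, which argues against that cause for them. A difference between single cultures, such as density at harvest, cannot be told apart from an effect of the oligonucleotide, because each group holds 1 library.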
